A study of Mus musculus with 31 samples.

How the data were processed

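Liver RNA of 31 BXD strains was measured on 2-colour glass arrays of 23040 features, with 1 array per strain. BXD strains are recombinant inbred mice derived from a cross of C57BL/6J and DBA/2J, so that each strain is fixed for 1 of the parental alleles at a locus. Per the labels' protocols, the RNA of 3 male mice aged 8 weeks was pooled for each strain and labelled with Alexa Fluor 647, a pool of 9 C57BL/6J mice labelled with Alexa Fluor 555 served as the reference on all arrays, and 20 ug of RNA was labelled for each. A spike-in RNA mix is listed with the reference RNA only, and all mice were male per the labels. Dyes were not exchanged on any array. A p-value over the 31 strains measures the spread between strains, since no strain had a second array.

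The authors deposited normalized log ratios, made with limma and R 2.0.0 per the submitters' processing notes, and these were read as log2 of strain over reference. The background correction and the normalization steps are not given in the sources used here, and neither are the log base and the direction of the ratio. The reading is likely because the strain RNA was in the red channel and limma forms red over green. No 2 arrays correlated clearly below 0, the lowest r over all probes being -0.04. The sorted values of any array differed from those of the first by at most 0.000256, so the arrays had been brought to 1 common distribution before deposit. Its median was -0.001 and its SD 0.51 on every array. No intensities were used, so signal over background and saturation are unknown, and the number of arrays limits the precision.

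Of the features, 1275 were empty on every array, among them 232 named Gapdh, and the other 21765 had a value on all 31 arrays and were tested. The platform annotation gave 1 gene for 16642 of the probes tested, several for 134 and none for 4989. Names were updated by gene ID from a RefSeq table of assembly GRCm38.p6, which held 15964 of the probes with 1 gene, and older names were kept for the rest. The table served for names and for the order of genes along chromosomes only. Probes with several genes were not named.

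The mean over strains was tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept, lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The reference is the only C57BL/6J RNA, so this test leaves out the control's own spread, and an effect of the dyes on a probe adds to its mean. To find probes whose strains fall into 2 clusters, the largest share of variance explained by a split of the sorted values, with at least 6 strains in the smaller cluster, was set against 1000000 simulated normal samples of 31 values (one-sided). For 36 gene lists written before the data were examined, probes of a gene were averaged, and the 32 lists with at least 5 measured genes were tested with camera (correlation 0.01) and fry. Co-variation of a list was the mean pairwise Pearson r across strains, set against 10000 random lists matched on SD (one-sided). A strain's score for a list was the mean of its members, each centred on its median. Neighbouring genes were adjacent measured genes on a chromosome, and their mean r was set against 10000 shuffles of the gene places.

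The genes named were chosen by a rule fixed beforehand. It took, among probes past the threshold with 1 gene, a symbol that is no clone name and the same sign in at least 25 strains, the 12 genes with the highest and the 12 with the lowest mean, then the 15 genes with the largest SD and up to 15 with the largest share explained by 2 clusters, up to 4 members of a list by absolute mean and up to 4 by SD, up to 10 genes for the strain sets, and every measured member of the lists of parental differences and of the Y-linked list. The rule's words on the largest SD were read as asking for a usable name only. A stricter reading, with a passing mean and 25 strains of the same sign, would have kept 7 of these 15 genes. Other genes are said to have been chosen later, and the agreement of probes of a gene, the every 8th places and the 4 arrays that stood apart were examined only after the values were seen.

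Tests were tried on simulated values with the SDs of the real probes. For the panel mean, over 21765 probes, 35 of 50 probes changed by 0.2 on the log2 scale, 47 of 50 changed by 0.5 and all 50 changed by 1 were called, with 18 calls among 21565 unchanged probes. For the strain sets, over the same number of probes, 3 of 50 changed by 0.2, 32 of 50 changed by 0.5 and 48 of 50 changed by 1 were called, with 10 calls among 21565 unchanged probes. In both simulations the noise was independent between probes and no array stood apart. Calls among unchanged probes therefore do not give the error rate in the real values. For the 2-cluster test, over 5000 simulated probes, 16 of 50 were called with clusters 4 SD apart and all 50 with clusters 6 SD apart, with 6 calls among 4850 probes without clusters. Alternatives chosen before the data were examined were centring, quantile normalization, array weights, rank tests, filters, other cluster sizes, principal components removed, Spearman correlation and each strain left out. Alternatives chosen after seeing the data were a correction for place (each value minus its array's median at the same place of all blocks of 480 features), leaving out every 8th probe, and leaving out strains 23, 28, 40 and 42.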

Results

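Pooled liver RNA of 31 BXD strains was compared, strain by strain, with 1 pooled C57BL/6J liver RNA. The 31 strains formed a single group with 1 array each, numbered between BXD1 and BXD42, and 21765 probes had a value on every array. Values are log2 ratios, in the likely direction of strain over reference, and means are given ± SE over 31 strains. The comparisons asked which transcripts differed from the C57BL/6J reference across the panel, which varied between strains, and which gene groups varied together. Probes of 1 gene did not share their panel mean, so gene names stand for single probes.

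Mt1, Ang, Apcs and Hp were among the 12 named genes with the highest panel means. The metal-binding metallothionein Mt1 was 3.86-fold above the reference (1.95 ± 0.20), the ribonuclease angiogenin, Ang, stood at 1.32 ± 0.07, the pentraxin Apcs at 1.21 ± 0.15 and haptoglobin, Hp, which binds free haemoglobin, at 1.15 ± 0.11. All 4 were above 0 in 31 of 31 strains, and Mt1 ranged from 0.09 in strain 23 to 3.65 in 6 strains (15, 20, 22, 33, 38 and 39). That value is the highest on every array, so the mean and range of Mt1 are capped by the common distribution. The other highest means were those of Haghl, Fam98c, Npr2, Lrrc56, Strn4, Spink12, Cst13 and Vps13b, down to 1.12 for Vps13b. Spink12 and Cst13 were above 0 in 30 of 31 strains and the others in all. The second probes of Npr2 and Vps13b had means of 0.17 and 0.02 (looked up after these genes were named).

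The 12 lowest named means were those of Ccdc91, Ifi204, Senp2, Ahnak, Vmn1r44, Nrcam, Gtf3c6, Iqcg, Ogfrl1, Gkn3, B3galt1 and Cryab, from -2.35 for Ccdc91 to -2.13 for Cryab. All 12 probes had an identifier that was a multiple of 8. Such probes, 2532 in number, had a median panel mean of -0.58, against 0.04 for the other 19233, and made up 85.3% of the 763 probes called with a mean of -1 or lower. After correction for place, all 12 stayed below the reference, Ccdc91 at -0.93, Ifi204 at -1.81 and Cryab at -1.61. They were picked as the lowest means and the correction subtracts the median of each place, so this does not show lower expression. The correction also raised other every 8th probes. Such probes made up 7 of the 12 highest corrected named means, Egln3 going from 0.11 to 1.42 (chosen after the values were seen). The second probe of Senp2 and of B3galt1 lay above 0 (0.38 and 0.56, looked up after these genes were named). Ahnak had 4 probes, and its others are not given here. Outside these places, Scd1, the desaturase that makes oleate, had one of the lowest means, -1.83 ± 0.16, and was below 0 in 31 of 31 strains (named after its value was seen).

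Probes of 1 gene did not share their panel mean (examined after the values were seen). The 326 probes of genes in the liver lists had a median SD of 0.32, against 0.24 for all probes, a difference that was not tested, and the SDs of 2 probes of a gene had a rank correlation of 0.018 across genes. The panel means of the 902 genes with exactly 2 probes had r = -0.06 across genes, which are not independent replicates, and 47.2% of these genes had means of the same sign. Across strains, 2 probes of a gene had a median r of 0.011, against 0.007 for probes of different genes paired at random. Only 19 of the 902 pairs had an SD of at least 0.4, so this rests mostly on probes that varied little. Those 19 had a median r of -0.012, against -0.19 for unrelated probes. The 4 probes of Trf had r between 0.17 and 0.75 across strains, with panel means between -0.67 and 0.17. A value given for a gene with 1 probe is therefore a value of that probe.

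**Figure D1:**
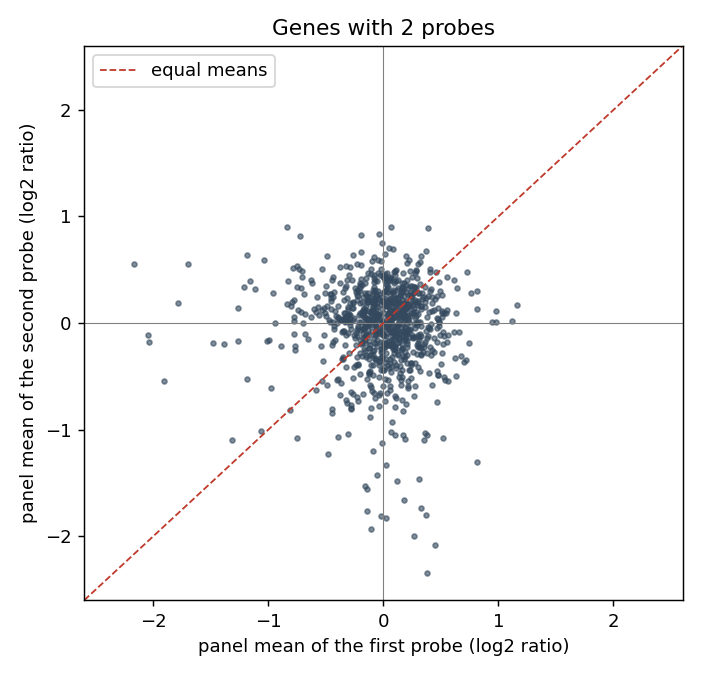
Panel mean (log2 ratio, strain over reference) of the first probe on the horizontal axis and of the second probe on the vertical axis, for the 902 genes with exactly 2 probes; each point is a gene and the dashed line marks equal means. The points do not follow the line (r = -0.06 across genes).

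In limma's test of the panel mean, 16325 of the 21765 probes passed, 8141 higher and 8184 lower than the reference. In all 31 strains, 784 probes were above 0 and 976 below, of which 430 were every 8th probes. The count fell to 7229, with 3187 higher and 4042 lower, when the test asked for a mean beyond 0.2. Because probes of a gene did not share their mean, the count is one of probes, and no number of genes that differed follows from it.

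Strain-specific levels were widest for a mixed set of probes. Among named probes, Bid, a pro-apoptotic BCL2 family member, had the largest SD, 1.22, followed by Terb2, the uridine phosphorylase Upp2, Mt1, Chrna4, Fpr2, Gadl1, H2-DMb2, Ptger3, Tuba4a, Mfsd14b, Rpl34, Tyk2, Satl1 and Rab43, the last at 1.07. H2-DMb2, a class II histocompatibility gene, ranged from -3.24 in strain 38 to 3.65 in strain 18, and Ptger3 was also lowest in strain 38, at -3.84. Like 3.65, -3.84 is the limit of the common distribution on every array, reached by Tuba4a in strain 14 too. Bid, Gadl1, Chrna4, Tuba4a and Mfsd14b were lowest in strain 14. Chrna4 had the highest value of the array in strains 23 and 40, which stood apart, and its mean was 0.32 with and -0.03 without the 4 strains. The second probes of Chrna4 and Tuba4a had means of 0.37 and 0.64, where the named probe of Tuba4a had -1.19. H2-DMb2, Rpl34, Tyk2 and Satl1 each had the array's highest value in 1 strain, and Rab43 was lowest in strain 23. Over all probes the median SD was 0.24, and 42 probes had an SD of 1 or more. Each strain had 1 array, so no extreme value has a replicate check.

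A split of the strains into 2 clusters explained enough variance in 15 probes to pass the threshold. The 7 with a usable gene name were Upp2 (92.0% of its variance), Igkv4-68, Trim21, Cnot4, Tcrb-V8.2, Tmem70 and Gcsh, which encodes the H protein of the glycine cleavage system (87.3%). The highest share, 93.4%, was that of probe 12855, which has no gene listed and lay below -1 in 11 strains, down to the lower limit of the array. Upp2 lay below -1 in 24 strains and above 1 in 1 strain, and after place correction its mean was -0.26 and no longer passed. The annotation gives the name Tcrb-V8.2 to 151 probes and Igkv4-68 to 10. Of the 7 named probes, 6 were every 8th probes, all but that of Tcrb-V8.2. Strains 23, 28, 40 and 42 were all in the smaller cluster in 7 of the 15 probes. The count was 2 after place correction, both without a gene listed (probes 12855 and 19600). Without these 4 strains it was 8, of which 6 were among the 15. Of the 7 named probes, Tcrb-V8.2 alone then passed the 2-cluster test (adjusted p = 0.044), while Tmem70 had 0.083 and Upp2 0.74. At an unadjusted p under 0.05 there were 721 probes, where 1088.25 would be expected by chance.

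**Figure D2:**
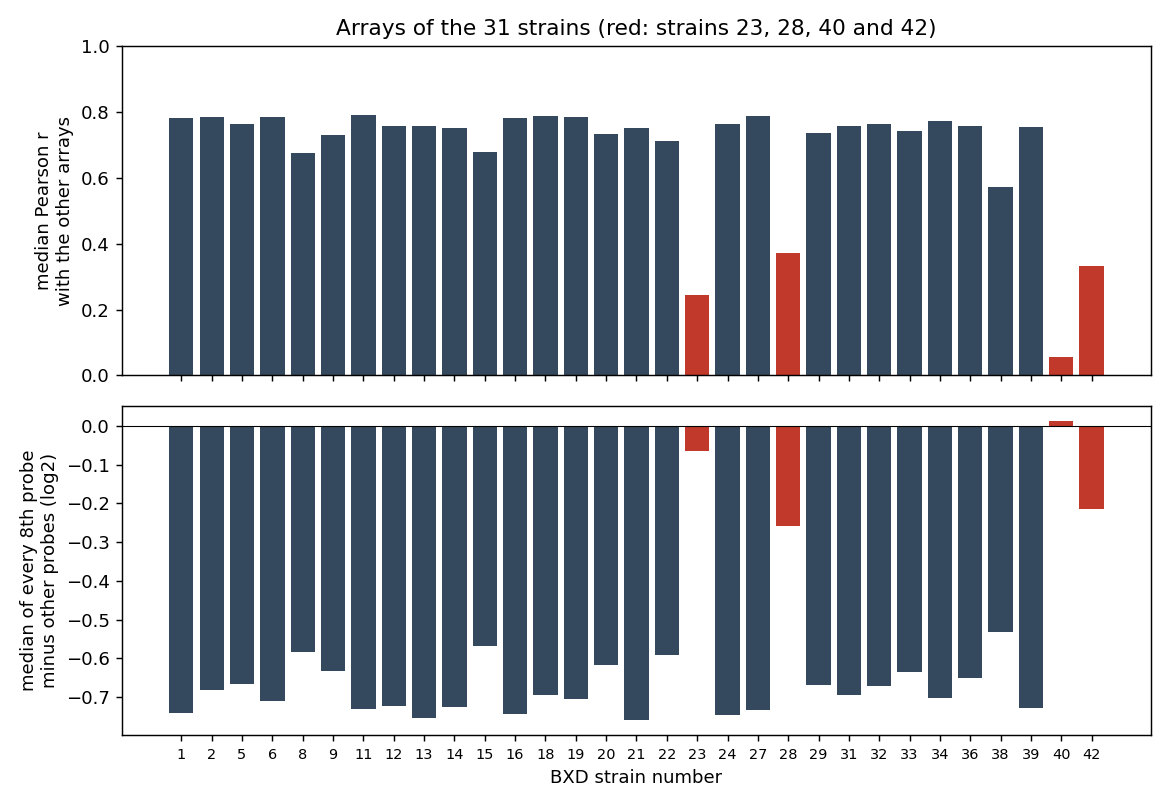
Median Pearson r of each array with the others (top) and the median log2 ratio of every 8th probe minus that of the other probes (bottom), 1 bar per BXD strain; strains 23, 28, 40 and 42 are red. The red bars reach r of 0.24, 0.37, 0.06 and 0.33, and the difference is near 0 in strain 40 (0.01).

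The arrays of strains 23, 28, 40 and 42 stood apart from the rest. Their median r with the other 30 arrays was 0.24, 0.37, 0.06 and 0.33, against 0.57 for strain 38 and at least 0.67 for the remaining 26. Pairs among the other 27 arrays had a median r of 0.76.

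In the panel mean, genes for ribosomal proteins and for oxidative phosphorylation were mostly above the reference, but no list passed the camera test over 32 lists. Over all 15095 genes, 38.5% were higher and 36.4% lower, and the counts of each list below should be read against these shares. Of 64 genes of cytosolic ribosomal proteins, 35 were higher, 10 lower and 19 did not pass (adjusted over the list alone, 35 and 9), with Rpl10a at 0.80 ± 0.06, Rps29 at 0.75 ± 0.08, and Rpl39 and Rpl39l, both every 8th probes, at -1.03 and -0.92. The list had an adjusted p = 0.069, and 0.90 with an estimated correlation. Of 72 oxidative phosphorylation genes, 43 were higher, 15 lower and 14 did not pass (adjusted over the list alone, 43 and 15), with Cox6a1 at 0.75 ± 0.06 and Cox5a at 0.74 ± 0.07 among the higher, and Ndufb10 (-1.26) and Ndufa8 (-1.10), both every 8th probes, among the lower. After place correction Ndufa8 had 0.12 and did not pass. Its list's adjusted p = 0.19. With place correction both lists passed camera, at adjusted p = 0.0029 and 0.020, but not with an estimated correlation (adjusted p = 0.80 for both).

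Lists of plasma protein genes and of lipid metabolism genes showed the same mixture. Of 36 complement and coagulation genes, 19 were higher, 7 lower and 10 did not pass (adjusted over the list alone, 19 and 7), with the anticoagulants Pros1 at 1.09 ± 0.09 and Serpinc1 at 1.06 ± 0.09, and the complement components C4b at 0.75 ± 0.09 and C9 at 0.73 ± 0.10 (camera adjusted p = 0.23). Of 29 acute phase genes, 14 were higher and 6 lower (adjusted over the list alone, also 14 and 6), and Socs3, a feedback inhibitor of cytokine signalling at an every 8th place, stood at -1.48 ± 0.09. Of 20 genes of cholesterol synthesis and uptake, 10 were higher and 3 lower (adjusted over the list alone, also 10 and 3), with squalene epoxidase, Sqle, at 0.78 ± 0.08, and Msmo1 at 0.68 ± 0.07 in 31 of 31 strains. Of 27 genes of PPAR-alpha targets and fatty acid oxidation, 13 were higher, 3 lower and 11 did not pass. Adjusted over the list alone, 13 and 3 were called, and the camera adjusted p was 0.35. Camera called no list, 4 of the 32 had an unadjusted p under 0.05, and fry, which tests whether the members move one way on balance and does not set a list against other genes, called 25.

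Markers of other cell types also went both ways in the panel mean. By strain, the adipose score was highest in strain 28 (0.37, with 13 of 14 members above their median), whose array stood apart. The exocrine pancreas score was highest in strain 24 (0.25, with 22 of 27 members above their median). Of 14 adipose tissue genes, 2 were higher and 7 lower (adjusted over the list alone, 2 and 7), led by Adipoq at -1.63 ± 0.13 at an every 8th place. Of 27 exocrine pancreas genes, 8 were higher and 11 lower (adjusted over the list alone, 8 and 11), with the amylases Amy2 at -1.06 and Amy1 at -0.99 and the proteases Prss1 at 0.85 and Ctrb1 at 0.73. Of 25 Kupffer cell and macrophage genes, 13 were higher and 6 lower (adjusted over the list alone, 13 and 6). All mice were male per the labels, and all 9 Y-linked genes passed: Uty (0.76, an every 8th probe, 1.57 after place correction), Eif2s3y (0.40) and Zfy2 (0.27) were higher, and Zfy1 (-0.52), Sry (-0.47), Kdm5d (-0.31), Uba1y (-0.30), Usp9y (-0.17) and Ssty1 (-0.12) were lower. Zfy1 did not pass after place correction (-0.06), nor Ssty1 without strains 23, 28, 40 and 42 (-0.07). Strain 38 had the lowest score for the Y-linked list (-0.39), with Uty at -2.88, while the other 8 genes ranked between 9 and 27 of 31 strains from the lowest. It also had the lowest score for growth hormone dependent genes higher in male liver (-0.61). There 13 of 20 members lay below their median, and that list did not vary together more than random lists. Strains 40 and 23, whose arrays stood apart, had the highest Xist (0.65 and 0.33) and the lowest Eif2s3y (-0.23 and -0.05). Other Y-linked genes went both ways in these strains. Kdm5d was among its highest values (-0.09 and 0.01), as was Sry (ranks 27 and 30 of 31 from the lowest). Ssty1 was among its lowest (ranks 5 and 1).

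Genes known to differ between the parents were measured by 1 probe each. Of those known to be lower in C57BL/6J, Glo1 had a mean of 0.38 ± 0.09 and ranged from -0.87 to 1.40, Nnt had 0.17 ± 0.05, H2-Ea 0.13 ± 0.06 and Alad 0.04 ± 0.03, the last with an adjusted p = 0.22. Of those known to be lower in DBA/2J, Hc, which encodes complement C5, had a mean of -0.46 ± 0.05 and was below 0 in 29 of 31 strains, Gpnmb had -0.29 ± 0.05 and Klrd1 0.03 ± 0.05 (adjusted p = 0.51). None of the 7 passed the 2-cluster test, so their signs were not taken as evidence for the direction of the ratio.

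Across strains, genes of 13 of the 32 lists varied together more than random lists. Ribosomal protein genes had the highest mean r, 0.26, against 0.002 in random lists, and strain 15 had their highest score (0.40, with 56 of 64 members above their median). Cholesterol synthesis and uptake (0.12), PPAR-alpha targets and fatty acid oxidation (0.12), the major histocompatibility complex (0.11), complement and coagulation (0.10) and cytochrome P450 families 1 to 3 (0.10) followed. Strain 38 was lowest for the histocompatibility list (-0.55), in which H2-DMb2, H2-Eb1 and H2-Ob were its lowest values, and strain 42 for cholesterol synthesis (-0.45). Strain 40 was lowest for complement and coagulation (-0.45), oxidative phosphorylation, ribosomal proteins, acute phase, conjugating enzymes and Kupffer cells. The arrays of strains 40 and 42 are among the 4 that stood apart, with a median r of 0.06 and 0.33. After those 4, the array of strain 38 had the next lowest median r, 0.57, and 0.44 after place correction.

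Oxidative phosphorylation, conjugating enzymes, bile acid genes, acute phase genes, urea cycle and amino acid catabolism, Kupffer cells and exocrine pancreas made up the rest of the 13, with mean r between 0.047 and 0.084 and adjusted p between 0.0032 and 0.049. Within the PPAR-alpha list, the fatty acid hydroxylases Cyp4a10 and Cyp4a14 had the largest SDs, 1.06 and 0.99. Without the 4 strains that stood apart, 12 of the 13 lists passed, and acute phase genes did not (adjusted p = 0.052). With place correction as well as without these strains, 10 of the 13 passed. With place correction 7 of the 13 lists passed, not among them conjugating enzymes, bile acid, acute phase, urea cycle, Kupffer cell and exocrine pancreas genes, and mean r went from 0.084 to 0.030 for Kupffer cells, from 0.067 to 0.040 for conjugating enzymes, from 0.064 to 0.046 for bile acid, from 0.061 to 0.044 for exocrine pancreas, from 0.061 to 0.056 for urea cycle and from 0.047 to 0.052 for acute phase genes. With 1 member per name family, ribosomal protein, cytochrome P450 and conjugating enzyme genes could not be tested, and 5 of the other 10 lists passed. Mean r was then 0.008 for histocompatibility genes (adjusted p = 0.54) and 0.10 for oxidative phosphorylation genes, which did not pass either (adjusted p = 0.31). Sequence shared by members of a family was not separated from shared expression.

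**Figure D3:**
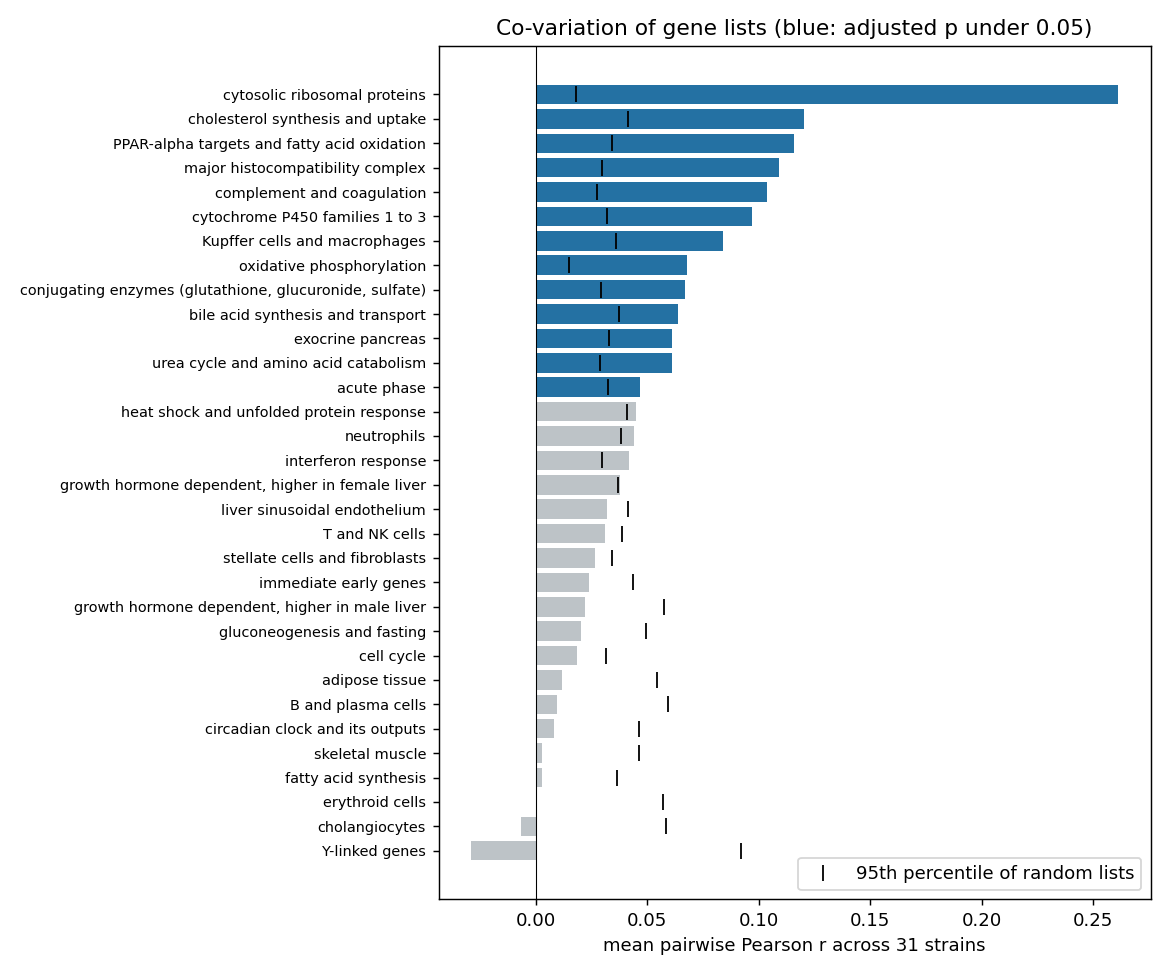
Mean pairwise Pearson r across 31 strains for each of 32 gene lists (bars, blue where the adjusted p is under 0.05), with the 95th percentile of random lists as black marks. Cytosolic ribosomal proteins reach 0.26, and 13 lists are blue.

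Genes next to each other on a chromosome were correlated very slightly more than genes placed at random. The 14603 adjacent pairs among 14624 genes had a mean r of 0.012, against 0.003 ± 0.002 (SD) in shuffled orders, with p = 0.0001 by permutation, the smallest that 10000 shuffles can give. The excess was also seen for genes 5 places apart (0.009, p = 0.0060 from 1000 shuffles) and not for genes 10 apart (0.005, p = 0.19). Without pairs that share the first 3 letters of their symbols, such as Cyp or Gst genes, mean r was 0.008 (p = 0.0078). With 3 principal components removed as well, p was 0.014 for adjacent genes, 0.14 for genes 2 apart, 0.052 for 3 apart and 0.013 for 5 apart, so no smooth decline with distance was seen there.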

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

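Chosen only after seeing the data were the place correction and the tests without every 8th probe or without strains 23, 28, 40 and 42. Centring, quantile normalization and the filter for probes on all arrays moved next to nothing, because the arrays already shared 1 distribution with no partly missing probe, so they say nothing about stability. For the panel mean, 16325 probes became 8119 when the lower SD group was left out, which removes probes from the test, and 7229 with a mean beyond 0.2, while leaving out each strain gave 16172 to 16500. Every 8th probe left out moved the share of higher calls from 49.9% to 56.9%. All 912 alternative values of the 24 genes named for their means kept direction and call. These genes were chosen for extreme means, so this says little about other probes. Over all probes, 6318 were called higher and 6351 lower both with and without place correction, and 824 passed both ways in opposite directions. For 2 clusters, 15 probes became 138 with at least 4 strains in the smaller cluster, 7 with at least 9 and 1 with 3 principal components removed, and 2 with place correction, 1 without every 8th probe, 8 without the 4 strains and 4 with both changes. For gene lists in the panel mean, 0 became 2 with place correction and 2 with place correction without the 4 strains. For co-variation, 13 lists became 22 with 3 components removed and 5 with 1 member per name family (where 3 of the 13 could not be tested). They became 7 with place correction and 7 without every 8th probe. Without the 4 strains there were 17, 12 of them among the 13, and with both changes 12, 10 of them among the 13. The neighbour result stayed past its threshold in all 8 alternatives, with mean r from 0.0059 to 0.022, the last, without every 8th probe, against 0.012 in shuffled orders. For strains 33 to 42, 24 probes became 183 with array weights, 1 with the rank-sum test, 40 with place correction, 47 without every 8th probe, 5 without the 4 strains and 7 with both changes. Leaving out each strain gave 0 (strain 42) to 982 (strain 23), and moved the count by over 1.5 times for every strain except 2, 5 and 27. The cause was not tested. No intensities were used, so what signal over background limits is unknown. No paired analysis was possible because all samples form 1 group.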

Other observations

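The tests of the place correction, of names on other rows, of dyes, of parental alleles and of the correlations of the 4 arrays, and the gene pairs, were chosen only after the results were seen, and the comparison of strain sets was planned while its prediction was written later. Among 18 pairs of genes looked at for shared variation across 31 strains, the fatty acid hydroxylases Cyp4a10 and Cyp4a14 had r = 0.77 (rho = 0.78, permutation adjusted p = 9e-05 and 0.00018), and 0.77 without the 2 strains farthest from the median of Cyp4a10. The plasma proteins Hp and Hpx, which bind free haemoglobin and haem, had r = 0.75 (rho = 0.69, permutation adjusted p = 9e-05 and 0.00027), and 0.64 without the 2 farthest strains. The clock genes Arntl and Dbp went opposite ways (r = -0.46, rho = -0.62, permutation adjusted p = 0.020 and 0.0017), and r was -0.59 without the 2 farthest strains. The lipogenic genes Fasn and Acly had r = -0.53 (rho = -0.50, permutation adjusted p = 0.010 and 0.017), and -0.41 without the 2 farthest, while Fgb and Fgg, subunits of one protein, had r = 0.07 (rho = 0.18, permutation adjusted p = 0.78 and 0.38), 0.17 without the 2 farthest strains and 0.42 without strains 23, 28, 40 and 42. The sex-linked Xist and Eif2s3y had r = -0.66 (rho = -0.48, permutation adjusted p = 0.00042 and 0.019), -0.42 without the 2 farthest and -0.29 without the 4 strains, of which 40 and 23 had the highest Xist and the lowest Eif2s3y. Fdps and Sqle, of cholesterol synthesis, had r = 0.49 (rho = 0.49, permutation adjusted p = 0.019 and 0.017), 0.40 without the 2 farthest and 0.28 without the 4 strains. Of the 18 pairs, 6 passed by r, which are those given here except Fgb and Fgg, and 7 by rho, the 6 and Serpina1a with Serpina1b. The other 12 had r from -0.32 to 0.40, among them Saa1 and Saa2, Apoa1 and Apoc3, Fga and Fgg, and Psmb8 and Psmb9. Without the 4 strains r was 0.51 for Fga and Fgg and 0.29 for Saa1 and Saa2.

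Most probes passed the test of the panel mean, yet 2 probes of a gene did not share their mean. Place on the array is argued against as the whole cause, since the correlation of the means stayed at -0.049 after place correction, and names attached to wrong rows across the whole array are argued against by the mean r of 0.26 among ribosomal protein genes, above the 0.018 that is the 95th percentile of random lists. Wrong names on part of the rows stay open. A parental allele inherited differently by the strains is argued against as the whole cause for the 10.8% of passing probes that lay on 1 side of 0 in all 31 strains. An allele effect on top of a shift shared by the arrays could also keep all strains on 1 side, so it stays open. The Tcrb-V8.2 probe of the 2-cluster test was below 0 in 31 strains and still passed that test (adjusted p = 0.017). An effect of the dyes on each probe, or a difference of the reference pool, may account for shared means and cannot be told apart from them, since 0 arrays had exchanged dyes.

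Every 8th probe lay below the others, with identifiers in steps of 8 explaining 29.2% of the variance of the probe means, against 0.034% for steps of 7. Lower transcript levels of the genes named there stay open, since genes may have been placed by level. At these places 25.7% of the probes had means under -1, against at most 1.05% at any other place in 8. That describes the pattern and does not test its cause. Other probes of these genes cannot decide between level and place. Those 550 had a median of 0.019, where the genes' own 250 probes had -0.60. But probes of 1 gene did not share their mean anywhere on the array. Of the 48 blocks of 480 features, 44 held values at these places, and the every 8th probes had the lower median in all 44, consistent with a feature of printing or plates that repeats. The layout was not used, so which step produced it stays open.

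Strains 23, 28, 40 and 42 stood apart from the other 27. A weaker place effect is argued against as the whole cause, since the highest of their 4 median correlations with the other 27 was 0.30 after place correction. Independent noise is argued against for strains 23, 40 and 42, whose lowest r with one another exceeded their median r with the other 27 by 0.29; these 3 were picked after the correlations were seen, strain 28 does not join them (lowest r among the 4 arrays -0.02), and noise stays open for it. Ribosomal protein genes were more spread on each of these arrays, at least 1.39 times the median of the others, which may point to lower measurement quality, although 3 of the other 27 were above this too, strain 32 at 2.19 times. A shared processing day or a shared genotype stays open, as neither was in the labels, and no biological explanation was tested.

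Strains numbered 33 to 42 were bred later than strains 1 to 32, as is known of the panel and not given by the labels, and the hypothesis was that the sets differ in liver expression. limma called 24 probes between the 7 and 24 strains, 9 higher and 15 lower in the later set, while array weights gave 114 higher and 69 lower. Of 100 splits of the same sizes, 3 gave as many, the real one included, a share under 0.05. That share does not exclude chance, because the highest other split called 2578 probes against the real 24. Both other splits held strains 23, 40 and 42 together, which points to a structure of the arrays, so the count is not read as a difference between the sets. The named genes were Rpl39, H2-Q2, Dbp, Cldn23, Ttpal, Prdx6-ps2, Ccdc181, Syap1, Atp5a1 and Selenop, with a difference (later minus earlier strains) of 0.74 ± 0.16 (SE) for Dbp, a clock output gene, and -0.80 ± 0.16 for H2-Q2. After place correction Rpl39, an every 8th probe, and Syap1 had differences of 0.63 and 0.48 and did not pass (adjusted p = 0.071 and 0.068). Without strains 23, 28, 40 and 42, H2-Q2 alone of these 10 passed, at -0.47. Dbp (0.70), Ccdc181 (-0.63) and Selenop (0.43) kept differences near their first values with fewer strains. Differences shrank for Rpl39 (0.82 to 0.57), Cldn23 (-0.72 to -0.37), Ttpal (-0.72 to -0.40), Prdx6-ps2 (-0.68 to -0.37), Syap1 (0.57 to 0.34) and Atp5a1 (-0.56 to -0.32). Without strains 23, 28, 40 and 42 there were 5 calls, of which 2 were among the 24, and leaving out strain 42 gave 0 and strain 23 gave 982, so the number of calls may rest on single arrays.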
